A study of Oryza sativa Japonica Group with 40 samples.

How the data were processed

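RNA was extracted with TRIzol from whole roots of 40 plants and made into libraries with a NEBNext Ultra RNA kit, per the labels' protocols. Plants grew on sand with low phosphate fertilisation, and 10 biological replicates were named for each of 4 genotypes, per the labels. Whether reads were counted by strand is not given in the sources used here, so overlapping and antisense loci cannot be told apart. Reads shared between near-identical loci were not examined.

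Per the submitters' processing notes, the tools were FastQC 0.11.8, STAR 2.7.3a and featureCounts, and the build was IRGSP-1.0. The deposited counts are whole numbers of reads per locus, with 42189 loci in 40 columns, of which 9693 had no count in any library. The deposited FPKM values equal the count divided by the library total and a locus length, which agreed across libraries within a relative tolerance of 1e-06 at all 32496 loci with a value. The deposited TPM values equal the FPKM rescaled to the same sum in each library, within 4.7e-08. The counts were tested. FPKM served for that check, and TPM for that check and 1 alternative.

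Row identifiers were 42004 locus numbers and 185 gene predictions on unplaced sequence. None matched the reference gene table of 39387 genes (0 matches, assembly ASM3414082v1). The 146 genes in 16 lists fixed before the data were examined also matched 0 rows and 0 reference genes. The mycorrhiza marker score, the gene list tests and 25 families planned by description were therefore not run, and loci carry no names.

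The rule for named loci was fixed before the data were examined. It took, per comparison and direction, the loci called with a mean of at least 1 CPM and the largest absolute log2 fold change, with at most 2 bare identifiers. The same plan named LOC_Os11g26140 as ARK1 from prior knowledge, and it asked that no value be given unless the reference tied the row to the gene. The reference did not. The row is reported against that rule, and this was decided after its values were seen. The ARK2 row was not identified.

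Counts were analysed in R 4.3.3 with edgeR 4.0.16. Loci were kept by filterByExpr (24885 kept, 17304 left out), scaled by TMM and fitted over all 40 libraries with 36 residual degrees of freedom. The biological coefficient of variation was 0.483. Each of 7 comparisons used the quasi-likelihood F test with Benjamini-Hochberg adjustment within the comparison, and loci were called at an adjusted p of 0.05 or less. Standard errors were the absolute log2 fold change over the square root of F. Where a genotype had no read, the fold is a bound against 3 reads over its 10 libraries. Floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules. The floor of a library was 0.107 to 0.192 CPM. In each genotype the closest pair of libraries differed far beyond sampling noise (chi-square per degree of freedom of 21.6 or more).

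The test was checked on simulated counts with the real means, dispersions and library sizes. Among 24885 loci, changes were set only at loci with a mean of at least 1 CPM, so recovery at lower levels was not checked. For ark1-2 against the wild type, edgeR recovered 63% of 108 loci changed by 1 on the log2 scale and 96.7% of 92 changed by 3. Of its calls, 4.27% were false. On the same simulated data 14.4% of the calls of the DESeq2 Wald test were false. Loci were drawn independently of each other, so differences that a plant shows over many loci at once were left out. These shares of false calls need not hold for the deposited counts. On the deposited counts the planned DESeq2 run used all 32496 loci with a read, so test and filter changed together, and a run on the 24885 filtered loci was added after seeing the data. Unchanged groups were simulated 20 times in the same way, the wild type included, with loci drawn independently of each other.

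Alternatives were DESeq2 1.42.0 size factors and Wald test, no filter, a stricter filter, fits of only the genotypes compared, replicate blocks, limma 3.58.1 voom with sample quality weights, limma-trend on the deposited log2(TPM + 0.5), a minimum log2 change of 1, and 1 surrogate variable from sva 3.50.0. Leaving out 6 libraries, and each library in turn, was also added after seeing the data. Library measures were compared by permutation with 100000 resamples in scipy 1.17.1. The score of the gene set was also fitted by least squares in statsmodels 0.14.6 with genotype and 1 library measure, with a common slope, chosen after seeing the data. Named loci were searched for genotypes whose plants fell into separate sets of at least 2 plants, with a log2 gap over 2.5 after adding 0.1 CPM.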

Results

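The transcriptome of whole roots was measured in 40 rice plants (cultivar Nipponbare) inoculated with Rhizophagus irregularis, an arbuscular mycorrhizal fungus. Each of 4 genotypes was represented by 10 plants: the wild type, the ark1-2 mutant, the ark2 mutant and the ark1ark2 double mutant. The double mutant is mutated in both genes, but the sample titles do not say whether with the same alleles. ARK stands for arbuscular receptor-like kinase. Libraries held between 15602553 and 27927924 counted reads, and between 21238 and 27473 loci had at least 1 read. Over a whole genotype of 10 libraries, 3 reads corresponded to between 0.0135 and 0.0153 CPM (a read count relative to the TMM-scaled library total). Folds given below as at least a value are bounds against these 3 reads, as if each read were an independent molecule. Reads are not independent molecules, so the true minimum can be lower. Loci are given by the identifiers of the deposited tables, which do not pair them with names. They are therefore described by level and direction, without a function.

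The libraries differed in how evenly low counts were filled. In each library the most frequent low count per locus was located, and it ranged from 3 to 44 reads. In 6 libraries it was 14 or more: wild-type replicates 1, 3 and 7, ark1-2 replicate 3, ark2 replicate 9 and ark1ark2 replicate 8. The number of loci detected was 24271 ± 1261 (SD, n = 10) in ark1-2, 25320 ± 1609 (SD, n = 10) in the wild type, 25558 ± 1345 (SD, n = 10) in ark2 and 25837 ± 1518 (SD, n = 10) in ark1ark2. The difference between ark1-2 and ark1ark2 did not pass a two-sided permutation test after adjustment over 6 pairs of genotypes (p = 0.0215, adjusted p = 0.115).

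**Figure D1:**
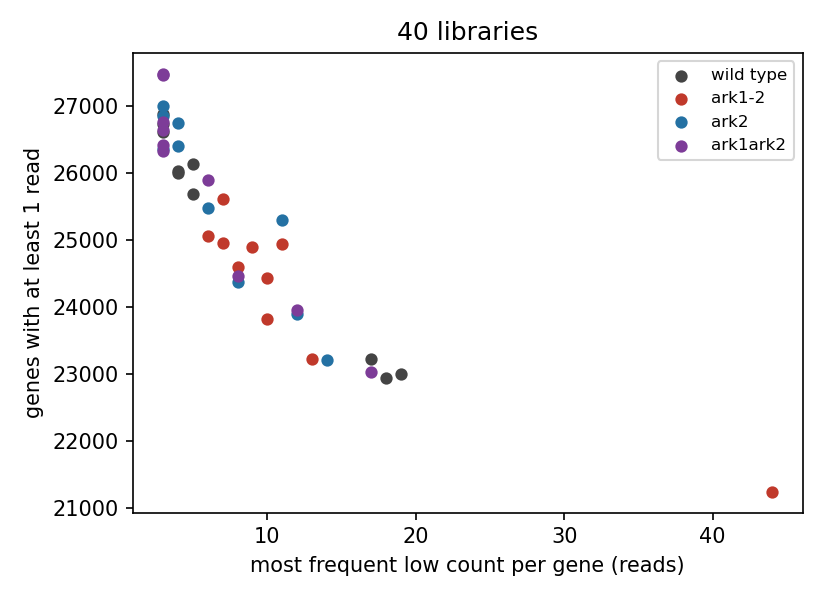
Loci with at least 1 read (vertical axis) against the most frequent low count per locus in reads (horizontal axis) for each of the 40 libraries, coloured by genotype. The library of ark1-2 replicate 3 lies at 44 reads and 21238 loci, apart from the others.

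The locus noted as ARK1 before the data were examined, LOC_Os11g26140, was nearly silent in both genotypes that carry an ark1 mutation. It reached 19.2 ± 20.2 CPM (SD, n = 10) in the wild type, 0.429 ± 0.701 CPM (SD, n = 10) in ark1-2, 6.05 ± 4.61 CPM (SD, n = 10) in ark2 and 0.431 ± 0.882 CPM (SD, n = 10) in ark1ark2. Plants of one genotype differed widely. In the wild type the locus ranged from no read in replicates 1 and 6 to 55.5 CPM in replicate 9, and in ark2 it ranged from no read to 13.5 CPM. Against the wild type the log2 fold change was -5.41 ± 1.14 (SE) in ark1-2 (edgeR adjusted p = 0.00571) and -5.53 ± 1.16 (SE) in ark1ark2 (edgeR adjusted p = 0.00654). Leaving out the highest plant lowered the mean to 0.238 CPM in ark1-2 (without replicate 1) and to 0.176 CPM in ark1ark2 (without replicate 6). In ark2 the log2 fold change was -1.67 ± 0.946 (SE), which did not pass the test (edgeR adjusted p = 0.788). Neither ark1-2 nor ark1ark2 differed from ark2 by this test (edgeR adjusted p = 0.0989 and 0.29). With voom and sample quality weights neither fall against the wild type passed the test (limma adjusted p = 0.471 for ark1-2 and 0.332 for ark1ark2).

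**Figure D2:**
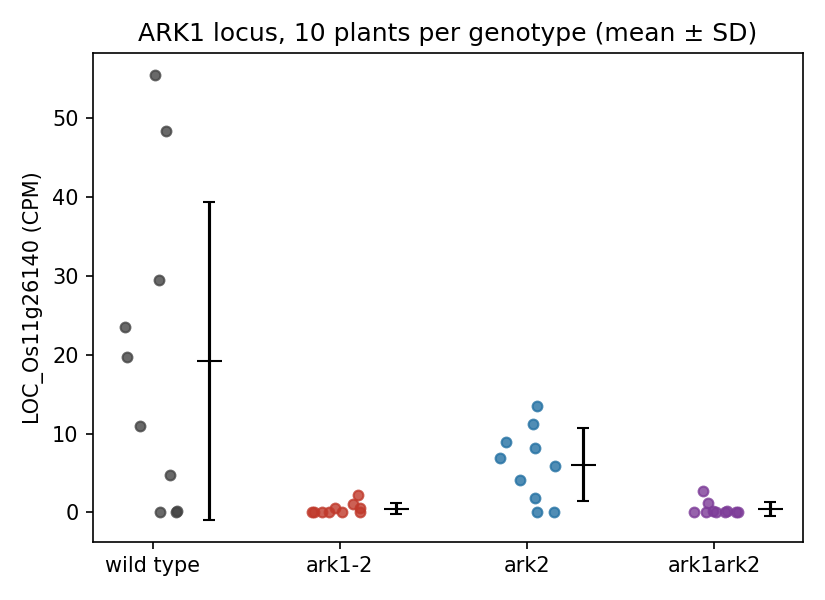
CPM of LOC_Os11g26140 (vertical axis) in each of 10 plants per genotype (points), with the mean and SD beside them. Wild-type plants spread from 0 to 55.5 CPM, while no plant of ark1-2 or ark1ark2 exceeded 2.73 CPM.

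The comparison of ark1-2 with the wild type asks how the root transcriptome under inoculation depends on ARK1. LOC_Os03g02470 rose from 0.0372 ± 0.118 CPM in the wild type, where 1 of 10 libraries had reads, to 253 ± 47.1 CPM (SD, n = 10) in ark1-2. LOC_Os08g27870 had no read in any wild-type plant and 25.1 ± 5.83 CPM (SD, n = 10) in ark1-2, at least 1641-fold higher. LOC_Os06g11230 had 5.42 ± 1.76 CPM (SD, n = 10) in the wild type and no read in ark1-2, at least 402-fold lower. LOC_Os06g34470 had 2.28 ± 2.84 CPM (SD, n = 10) in the wild type, from 7 of 10 libraries, and no read in ark1-2, at least 169.6-fold lower. Of 24885 loci tested, 510 were called by edgeR's quasi-likelihood test at an adjusted p of 0.05 or less, 172 higher and 338 lower. Their median absolute log2 fold change was 1.02 for the higher and 1.76 for the lower loci, and 321 changed by at least 1 on the log2 scale. This count depended on single plants: it was 192 without wild-type replicate 9, 315 without wild-type replicate 8, 338 without ark1-2 replicate 8 and 311 without ark1-2 replicate 9. The balance of directions was not stable either. It was 96 to 96 without wild-type replicate 9, and more loci were higher than lower with voom and sample quality weights (221 and 207), with 1 surrogate variable (127 and 116) and with limma-trend on the deposited TPM (330 and 227).

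In ark2, LOC_Os03g02470 was also higher than in the wild type, at 249 ± 55.2 CPM (SD, n = 10). LOC_Os03g43100 had no read in any wild-type plant and 19.0 ± 4.86 CPM (SD, n = 10) in ark2, at least 1242-fold higher. LOC_Os06g11230 had no read in ark2, at least 401-fold lower than in the wild type. LOC_Os11g36790 fell from 16.92 ± 4.39 CPM (SD, n = 10) to 0.669 ± 0.489 CPM (SD, n = 10), with a log2 fold change of -4.66 ± 0.414 (SE, edgeR adjusted p = 8.01e-11). In all, 108 loci were called, 70 higher and 38 lower, and 75 changed by at least 1 on the log2 scale. Leaving out any library in turn gave between 95 and 126 loci. The majority of higher loci turned with the DESeq2 Wald test (98 higher and 116 lower) and nearly vanished with voom and sample quality weights (103 and 98).

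In ark1ark2, where mutations of both genes are combined, 3 of the 4 loci with the largest changes were those named for ark2. LOC_Os03g02470 reached 199.7 ± 69.8 CPM (SD, n = 10) and LOC_Os03g43100 reached 18.01 ± 5.18 CPM (SD, n = 10), at least 1180-fold above the wild type. LOC_Os06g11230 had no read, at least 380.2-fold lower than in the wild type. LOC_Os04g47390 fell from 30.4 ± 43.3 CPM (SD, n = 10) in the wild type to 0.359 ± 0.595 CPM (SD, n = 10), a log2 fold change of -6.37 ± 1.22 (SE, edgeR adjusted p = 0.00178). Wild-type replicate 9 alone held 141.3 CPM, and without it the wild-type mean was 18.1 CPM. Without ark1ark2 replicate 2 the mutant mean was 0.198 CPM. The call of LOC_Os04g47390 was lost with voom and sample quality weights (limma adjusted p = 0.315). Of the 366 loci called, 141 were higher and 225 lower, and 191 changed by at least 1 on the log2 scale. The count was 156 without wild-type replicate 9, 567 without wild-type replicate 1, and 209, 750, 237 and 223 without ark1ark2 replicates 5, 6, 8 and 10. Without wild-type replicate 9 the balance turned to 88 higher and 68 lower, and with limma-trend on the deposited TPM to 409 higher and 153 lower.

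**Figure D3:**
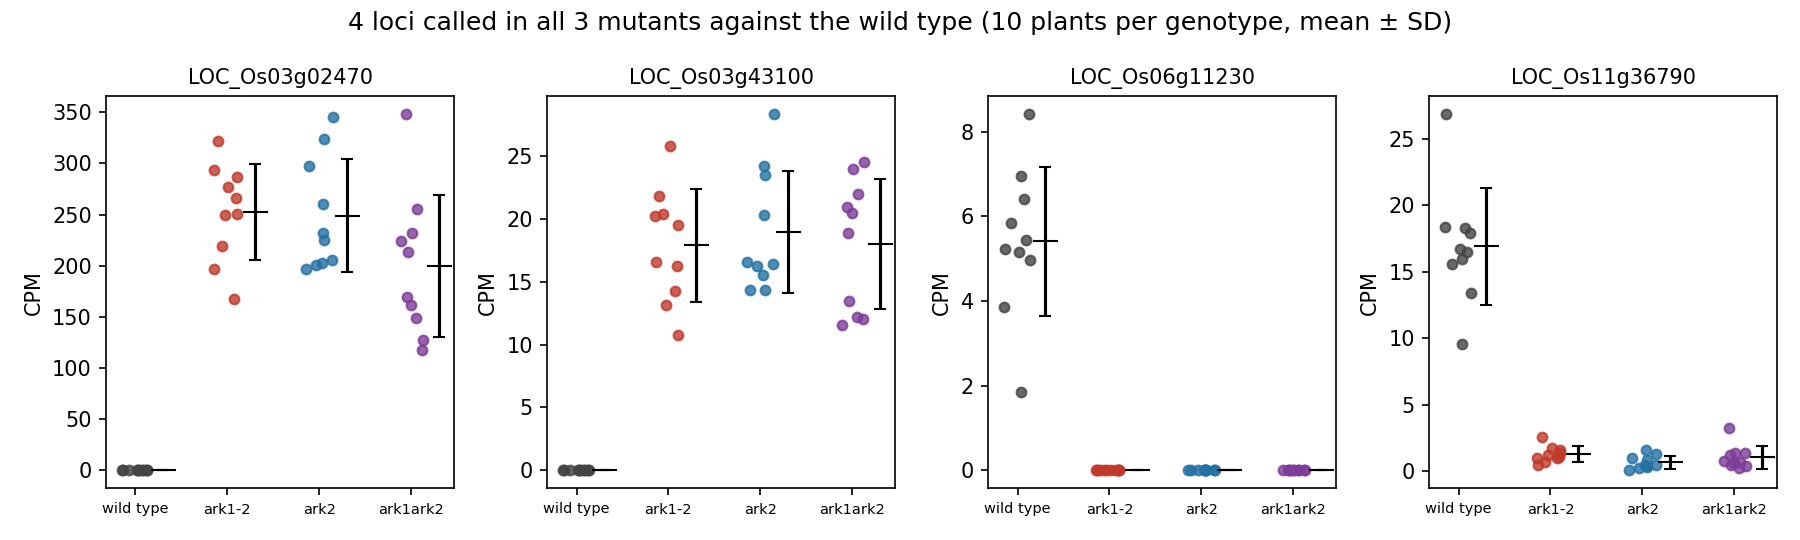
CPM (vertical axes) of LOC_Os03g02470, LOC_Os03g43100, LOC_Os06g11230 and LOC_Os11g36790 in each of 10 plants per genotype (points), with the mean and SD beside them. In the wild type LOC_Os03g02470 averaged 0.0372 CPM and LOC_Os03g43100 had no read, and LOC_Os06g11230 had no read in the mutants.

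The 3 mutants changed in the same direction at many loci. Called loci shared by ark1-2 and ark1ark2 numbered 82 higher and 110 lower, against 0.975 and 3.06 from independent lists of those sizes. The mutants ark1-2 and ark2 shared 51 higher and 15 lower loci, against 0.484 and 0.516, and ark2 and ark1ark2 shared 59 higher and 23 lower, against 0.397 and 0.344. In all 3 mutants 48 loci were higher and 14 lower. No locus was called in opposite directions in a pair of mutants. In 20 simulations of unchanged groups, which shared a wild type that was itself simulated, at most 1 locus was called in a comparison. Their shared count of 0 therefore gives no measure of what shared controls add to these lists. Because the comparisons share their controls, the wild-type plants were also split into odd and even replicate numbers. With odd plants for the first mutant of a pair and even plants for the second, ark1-2 and ark1ark2 shared 43 higher and 17 lower loci (0.265 and 0.248 from independent lists), ark1-2 and ark2 shared 35 and 7 (0.226 and 0.186), and ark2 and ark1ark2 shared 29 and 8 (0.102 and 0.0453). With the plants exchanged the shared loci were 47 and 25, 28 and 7, and 38 and 7. Loci that all 3 mutants share against the wild type include LOC_Os03g02470 and LOC_Os11g36790. They also carry any difference between the wild-type and mutant lines other than the ARK mutations, which the design does not separate. A difference of single lines can likewise lie behind loci changed in only some of the mutants.

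Across the 24885 loci, which are not independent replicates, the log2 fold changes against the wild type correlated at r = 0.81 between ark1-2 and ark1ark2, 0.70 between ark2 and ark1ark2 and 0.60 between ark1-2 and ark2. Unchanged groups simulated against a shared, simulated wild type gave mean values of 0.50, 0.504 and 0.502, with loci drawn independently. Structure among the real wild-type plants is not in these values. The SD of r over resampled libraries was 0.073, 0.094 and 0.0957. The covariances were 0.38, 0.25 and 0.236, against simulated values of 0.0824, 0.0833 and 0.0827. With the wild-type plants split, r was 0.567 and 0.57 for ark1-2 and ark1ark2, 0.42 and 0.428 for ark2 and ark1ark2, and 0.357 and 0.359 for ark1-2 and ark2. In the same order the covariances were 0.311 and 0.317, 0.187 and 0.183, and 0.165 and 0.176. The split also left fewer control plants per comparison, which lowers r through added noise.

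**Figure D4:**
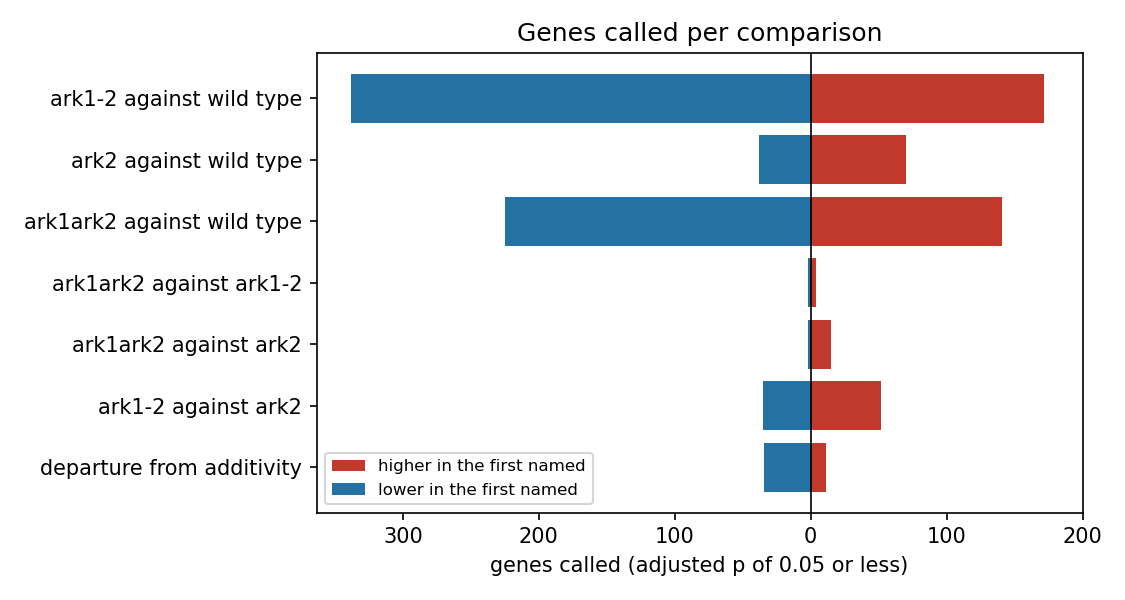
Number of loci called at an adjusted p of 0.05 or less (horizontal axis) in each of the 7 comparisons (vertical axis), with higher loci to the right and lower loci to the left. For the departure from additivity, right means above and left below the sum of the separate changes on the log2 scale. The comparison of ark1-2 with the wild type had 172 higher and 338 lower loci, and that of ark1ark2 with ark1-2 had 4 and 2.

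Few loci separated ark1ark2 from the mutants with a single mutation. Against ark1-2, LOC_Os02g52730 was higher in ark1ark2 (21.2 ± 16.0 against 0.649 ± 0.595 CPM, SD, n = 10), as was LOC_Os04g34600 (536 ± 238 against 58.4 ± 14.6 CPM, SD, n = 10). The ark1ark2 plants were split at LOC_Os02g52730, with 3 between 0.352 and 1.74 CPM (replicates 2, 6 and 7) and 7 between 13.0 and 41.4 CPM. At this locus the wild type had 0.80 ± 0.584 CPM and ark2 25.4 ± 9.49 CPM (SD, n = 10). LOC_Os04g43090 had no read in ark1ark2 and 7.24 ± 3.25 CPM (SD, n = 10) in ark1-2, at least 508-fold lower, and LOC_Os11g47140 was lower (3.43 ± 3.42 against 55.6 ± 13.2 CPM, SD, n = 10). For LOC_Os04g34600 the wild type averaged 652 CPM and ark2 647 CPM, and for LOC_Os11g47140 they averaged 5.14 and 6.29 CPM. At both loci ark1-2 stood apart, although ark1ark2 is mutated in ARK1 too. A difference of allele, or a difference of the ark1-2 plants other than the ark1 mutation, was not separated. In all, 6 loci were called, 4 higher and 2 lower, with 1605 at an unadjusted p under 0.05. The balance turned to 10 higher and 27 lower with voom and sample quality weights, 4 and 6 with the replicate block, 4 and 5 with 1 surrogate variable and 14 and 15 with the DESeq2 Wald test on the filtered loci.

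Against ark2, LOC_Os11g31630 had 3.25 ± 1.73 CPM (SD, n = 10) in ark1ark2 and no read in ark2, at least 241-fold higher. LOC_Os11g24890 had 881 reads in ark1ark2 and 3 in ark2, a ratio of 310.1 with a 95% counting interval of 106 to 1507. All 3 ark2 reads came from replicate 4, and the interval leaves out the spread between plants. LOC_Os11g31630 and LOC_Os11g24890 had no read in the wild type and 2.23 and 4.17 CPM in ark1-2. Whether an ark1 mutation or another difference of the lines carrying it sets them apart was not tested. LOC_Os01g57890 was lower in ark1ark2 (12.5 ± 4.81 against 28.5 ± 8.16 CPM, SD, n = 10), as was LOC_Os09g21380 (63.9 ± 15.7 against 106.7 ± 35.2 CPM, SD, n = 10). The last call, at an edgeR adjusted p of 0.0384, was lost in several alternative fits. In all, 17 loci were called, 15 higher and 2 lower. With voom and sample quality weights 14 were higher and 8 lower, and 9 of the 17 calls were kept. With limma-trend on the deposited TPM 17 were higher and 5 lower, and 16 were kept. A fit of only these genotypes called 6 higher and 1 lower, and kept 6.

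The mutants with a single mutation were also compared with each other. LOC_Os07g26100 had 91.1 ± 18.1 CPM (SD, n = 10) in ark1-2 and 0.239 ± 0.25 CPM (SD, n = 10) in ark2. LOC_Os11g31630 had 2.23 ± 1.53 CPM (SD, n = 10) in ark1-2 and no read in ark2, at least 165.3-fold higher. LOC_Os02g06940 had no read in ark1-2 and 4.96 ± 4.30 CPM (SD, n = 10) in ark2, at least 369-fold lower, and LOC_Os03g31560 had no read in ark1-2 and 3.69 ± 2.75 CPM (SD, n = 10) in ark2, at least 274-fold lower. These means cover unlike plants. At LOC_Os02g06940, 4 ark2 plants (replicates 3, 4, 6 and 10) had 0.215 CPM or less and the other 6 had 6.77 to 9.62 CPM. The same 4 plants had 0.894 CPM or less at LOC_Os08g27870, where the other 6 had 15.7 to 32.2 CPM. At LOC_Os03g31560, ark2 replicates 3 and 6 had no read, nor had ark1-2 replicates 2 and 3 at LOC_Os11g31630. The test called 87 loci, 52 higher and 35 lower in ark1-2, but among loci that changed by at least 1 on the log2 scale 26 were higher and 30 lower. Without the 6 libraries with a high most frequent count, an alternative chosen after seeing the data, 278 loci were called. The count was 50 without ark1-2 replicate 9, 46, 54 and 49 without ark2 replicates 1, 2 and 10, and 132 without ark1ark2 replicate 6.

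With the alleles taken to be the same, the change in ark1ark2 was set against the sum of the changes in ark1-2 and ark2 on the log2 scale. At 45 loci it departed from that sum, 11 above and 34 below. Of these, 36 were called in the same direction in all 3 mutants against the wild type. At each of the 36 the departure ran opposite to that direction, so that the combined change was smaller than the sum. A similar change in all 3 mutants gives this direction whatever its origin. Where each mutant already had no read, ark1ark2 could not reach the sum of the log2 falls. Where the wild type had no read, the floor set the size of each rise. LOC_Os03g02470 was among the 36, but its 8 wild-type reads all came from replicate 5, so the size of its departure is not given. LOC_Os11g36790 was another, with a departure of 4.36 ± 0.539 (SE, edgeR adjusted p = 7.9e-07). At LOC_Os04g34600 the departure was 3.21 ± 0.344 (SE, edgeR adjusted p = 1.95e-08), where the level was low in ark1-2 alone. The departure at LOC_Os04g43090 (edgeR adjusted p = 0.000267) was not called without ark2 replicate 2. On the deposited TPM 21 loci lay above and 35 below.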

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

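All tests of explanations in this part, the definition of all-or-none loci and the choice of the 6 libraries left out were chosen after the results were seen. A value far from the rest of its genotype was found in 13 of 92 groups of 10 plants tested. A rate of 1 in 20 would give about 4.6, but that rate does not hold here. Plants without a read share 1 value on the log2 scale, so a group with reads in a single plant was always flagged. The named loci were also picked for large changes.

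The most frequent low count in ark1-2 replicate 3 was 44 reads. The most abundant locus held 17.4% of the counts in wild-type replicate 3 and 15.5% in ark1-2 replicate 3. Among named loci, on the log2 CPM scale, LOC_Os03g02470 stood high in wild-type replicate 5 at -1.255, and LOC_Os06g11230 stood low in wild-type replicate 1 at 0.931. LOC_Os06g34470 stood high in ark1ark2 replicate 6 at 0.733, LOC_Os04g34600 low in ark1ark2 replicate 5 at 6.59 and LOC_Os11g47140 low in ark1ark2 replicate 8 at -4.41. LOC_Os04g43090 stood low in ark1-2 replicate 3 at -3.485 and high in ark2 replicate 2 at -0.0745. LOC_Os11g24890 stood high in ark2 replicate 4 at -2.52 and low in ark1ark2 replicate 6 at 0.434, and LOC_Os01g57890 low in ark2 replicate 6 at 3.64.

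The responses of ark1-2 and ark2 differed at 87 loci, and 45 loci departed from additivity. Whether chance groupings of the same libraries give such counts was examined with 100 splits per comparison, the real one included. For ark2 against the wild type (108 loci), 1 split reached the real count, with 4 the highest of the others. For ark1ark2 against the wild type (366 loci) it was 1, with 50 the highest other. For ark1-2 against ark2 (87 loci) it was 1, with 1 the highest other, and for additivity (45 loci) 1, with 0 the highest other. For ark1-2 against the wild type (510 loci), 2 splits reached the count and 1 of them called 960. For ark1ark2 against ark1-2 (6 loci) 2 splits did, the other calling 45, and against ark2 (17 loci) 2 did, the other calling 55. Apart from additivity, the share of splits reaching the real count was under 0.05 in each comparison, which argues against chance at that level. That share is known only roughly where another split called more loci. For additivity the labels of all 4 genotypes were mixed, which also removed the differences between the wild type and the mutants. Those splits cannot tell how often chance gives departures beside such differences. What set apart the splits that called more loci than the real one was not tested.

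At 16 loci all plants of one genotype had 10 or more reads and all plants of another had 3 or fewer. At 8 of them the wild type was off and all 3 mutants were on, and at 1 the reverse held. At the wild-type or mutant level at least 102.9 molecules were expected where 0 reads were seen. Molecules were estimated as reads divided by the most frequent low count of each library. At LOC_Os06g11230 in ark1-2, 1207 reads but only 131.1 such molecules were expected. A fold bound set against 3 reads is therefore larger than one set against 3 molecules. The requirement of 10 or more reads in every plant largely fixes that expectation in advance, so it does not decide on low library complexity. Loss of either ARK gene, and a difference between the lines other than the mutations, such as in seed stock, both stay open for these 9 loci and were not tested. The same holds for the 48 higher and 14 lower loci called in all 3 mutants and for the 36 of 45 non-additive loci among them.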

How the results depend on the processing

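Leaving out libraries and running DESeq2 on the filtered loci were chosen after seeing the data, and the other alternatives before the data were examined. The planned marker score and gene list alternatives were not run. Except where the construction of the alternative shows it (fewer loci, fewer samples, an added threshold), the cause was not tested. The DESeq2 Wald test on all 32496 loci with a read called more in each comparison: 906 for ark1-2, 214 for ark2 and 844 for ark1ark2 against the wild type, 35 for ark1ark2 against ark1-2, 43 against ark2, 382 for ark1-2 against ark2 and 79 for additivity. On the 24885 filtered loci it called 888, 207, 837, 29, 32, 367 and 74 in that order. Voom with sample quality weights called 201 for ark2 and 728 for ark1ark2 against the wild type, 37 for ark1ark2 against ark1-2 and 569 for ark1-2 against ark2. Fits of only the genotypes compared gave 129 for ark1ark2 against the wild type, 3 and 7 for ark1ark2 against ark1-2 and ark2, and 163 for ark1-2 against ark2. A log2 change of at least 1 left 321, 191 and 56 for ark1-2 and ark1ark2 against the wild type and ark1-2 against ark2. With 1 surrogate variable there were 243 for ark1-2 against the wild type and 53 against ark2. Limma-trend on TPM called 562 for ark1ark2 against the wild type. Without the 6 libraries, ark1-2 against ark2 had 278. Apart from the replicate block and single libraries left out, given next, the other counts stayed within 1.5 times.

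No clear pairing by replicate number was seen: deviations of same-numbered plants correlated between -0.373 and 0.24. For ark1-2 and ark2 these correlations lay between 0.0284 and 0.146. Correlations of plants with unlike numbers were not summarised, so a weak pairing is not excluded. With the replicate block, ark1-2 against the wild type had 295 loci and ark1ark2 against ark1-2 had 10, and the other counts stayed within 1.5 times. At most 1 of 10 libraries was closest to its own number.

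Leaving out each library in turn gave 192 to 684 loci for ark1-2, 95 to 126 for ark2 and 156 to 750 for ark1ark2 against the wild type, 6 to 8 for ark1ark2 against ark1-2, 14 to 23 against ark2, 46 to 132 for ark1-2 against ark2 and 41 to 54 for additivity. With split controls, correlations fell to 0.357 and 0.359 for ark1-2 and ark2, and to 0.567 and 0.57 for ark1-2 and ark1ark2. For ark2 and ark1ark2 they fell to 0.42 and 0.428. Removing shared controls lowers r by construction, but so does the noise of fewer control plants per comparison. These parts of the fall were not separated. Over the named loci, of the values called as reported, 329 kept their call under other alternatives and 17 lost it, and 1183 kept it with a library left out and 17 lost it. Calls lost with voom and sample quality weights included LOC_Os08g27870 and LOC_Os06g34470 in ark1-2 against the wild type (limma adjusted p = 0.0797 and 0.0973). Others were LOC_Os02g52730 in ark1ark2 against ark1-2 (0.419), and LOC_Os07g26100 and LOC_Os02g06940 in ark1-2 against ark2 (0.12 and 0.154). With the replicate block LOC_Os06g11230 in ark2 against the wild type was lost (edgeR adjusted p = 0.0556). Of the values not called as reported, none was called in an alternative, and 7 changed sign with a library left out. Those 7 were LOC_Os11g26140 in ark1ark2 against ark1-2, uncalled throughout, whose log2 fold change ran from -1.26 to 0.716 over the libraries left out and was above 0 in those 7 (0.0339, 0.0345, 0.0366, 0.0402, 0.0434, 0.114 and 0.716).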

Other observations

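The tests in this part were chosen after the data were seen. Loci lower in ark1-2 than in the wild type tended to rise and fall with LOC_Os11g26140 from plant to plant. Over wild-type plants their median r with it was 0.817, against 0.000473 for all loci, and over ark2 plants it was 0.764. For loci lower in ark1ark2 the medians over wild-type and ark2 plants were 0.689 and 0.555, and for loci lower in ark2 0.308 and 0.279. All of these loci were called against the same wild-type plants. The 338 lower calls in ark1-2 became 96 and 194 without replicates 9 and 8. These were the wild-type plants highest at LOC_Os11g26140 (55.5 and 48.4 CPM). The medians over wild-type plants are therefore partly built in by the selection, and all loci are no fair baseline. Over ark2 plants no median was taken for all loci. A set of 246 loci was taken from the ark2 plants alone, by an r of at least 0.9 with that row, which itself was left out. At that row 2 ark2 plants had no read (replicates 3 and 8) and 8 had 1.82 to 13.5 CPM. The choice of loci can therefore rest largely on those 2 plants, and it was not repeated without them. Of the 246, 86 were lower in ark1-2, 21 in ark1ark2 and 0 in ark2 (edgeR), and 0 were higher.

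The mean log2 CPM of the set, centred per locus, was 1.22 ± 2.02 (SD, n = 10) in the wild type, 0.868 ± 1.98 (SD, n = 10) in ark2, -1.15 ± 1.16 (SD, n = 10) in ark1-2 and -0.94 ± 1.66 (SD, n = 10) in ark1ark2. The wild type exceeded ark1-2 by 2.38 (permutation p = 0.00612, adjusted over 6 pairs 0.0367) and ark1ark2 by 2.16 (p = 0.021, adjusted p = 0.042). With an r of 0.8, 0.85 and 0.95 the difference from ark1-2 was 1.44, 1.83 and 3.15. Over the 10 wild-type plants the score followed LOC_Os11g26140 at r = 0.969 and rho = 0.988, each with permutation p = 1e-05, the smallest that the resamples can give, adjusted over 6 relations to 6e-05. Without replicates 1 and 6 r was 0.977, and over the 7 plants above 1 CPM it was 0.9695. Over ark1ark2 plants r was 0.949 (adjusted permutation p = 0.00072) and rho 0.855 (adjusted p = 0.00759), and r was 0.761 without replicates 2 and 6. Over ark1-2 plants r was 0.71 (adjusted permutation p = 0.0477) and rho 0.552 (adjusted p = 0.208), and r was 0.577 without replicates 1 and 5. LOC_Os11g26140 had reads in only 5 of 10 ark1ark2 plants and 4 of 10 ark1-2 plants. The relations within these mutants therefore rest on few plants with low levels.

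A candidate explanation is a root state, such as the extent of colonisation, that varies between plants and is lower where ARK1 is mutated. The largest adjusted p of the 4 differences between genotypes with and without an ark1 mutation was 0.0627, for ark2 and ark1ark2, so that explanation is left open. Low library complexity as the whole cause is argued against. With the log2 of the most frequent low count as a covariate, the wild type exceeded ark1-2 by 2.402 ± 0.823 (SE) and ark1ark2 by 2.153 ± 0.793 (SE), against 2.375 ± 0.777 and 2.163 ± 0.777 without it, and the smaller of the lower 95% limits was 0.5421. With the number of loci detected as the covariate the differences were 2.296 ± 0.815 and 2.202 ± 0.793 (SE), with 0.5923 as the smaller lower limit, which argues against fewer detected loci in the same way. Both calls were lost when the 6 libraries were left out, which left 7 wild-type plants and 9 of each mutant: the differences were 2.397 (exact permutation p = 0.0187, adjusted p = 0.112) and 2.029 (p = 0.0566, adjusted p = 0.113). Colonisation was not analysed here.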
